A study of Mus musculus with 20 samples.

How the data were processed

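RNA was measured in 20 samples of E2-10HA, a mouse hybridoma line that the labels describe as mature T cells. The labels put them in 6 groups. CRISPR control samples carried the empty lentiCRISPRv2 vector (n = 6), and H2A.Z guide samples carried the same vector with guide RNAs against H2afv and H2afz, the genes encoding the histone variant H2A.Z (n = 6). BioNICD samples expressed the bacterial biotin ligase BirA with a biotin-tagged Notch intracellular domain (NICD), either wild type (n = 2) or a form labelled as the DEP mutant (n = 2). NICD-ER samples expressed NICD fused to the ligand-binding part of the estrogen receptor and received for 24 hours either ethanol (n = 2) or the receptor ligand 4-hydroxytamoxifen, 4-OHT (n = 2). Groups and replicate numbers were taken from the sample titles. In 6 of the 8 CRISPR samples with replicate numbers from 3 upwards the description names another group than the title does, and the integrated plasmid goes with the title. All 6 titles of the H2A.Z guide samples carry the same number, so they are treated as samples of 1 line. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Of the CRISPR samples, replicates 1 and 2 of each group carry a treatment field in the labels and replicates 3 to 6 do not. This difference was taken as a sign of separate submission sets (set 1 and set 2), each with both groups.

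Per the labels' protocols, total RNA was depleted of ribosomal RNA and made into libraries with a stranded kit. The submitters' processing notes name FastQC, Trimmomatic, STAR, featureCounts, DESeq2 and the mouse genome build mm9. Per the file headers, the authors counted reads over exons and summed them per gene with featureCounts 1.5.0 and a UCSC mm9 gene annotation. The command recorded there sets no strand option, so reads from a gene and from an overlapping or antisense gene cannot be told apart. Versions of the other tools are not given in the sources used here. The deposited values are raw read counts for 24391 genes per sample, with no normalization. Reads shared between near-identical copies, as in the replication-dependent histone genes, the granzymes and the Serpina3 family, may be divided or lost in such counts, and values of single members of these families are uncertain. Gene coordinates come from the file headers' build, mm9. The reference genome at hand is another build and served only for the GC content of genes matched by symbol.

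The samples held between 10704131 counts (CRISPR control replicate 2) and 48238324 counts (BioNICD wild type replicate 1). Counting intervals and floors below cover counting error only, because reads without molecular identifiers are not independent molecules. Where every sample of a group had 0 counts, the fold difference is given as a lower bound against a floor of 3 counts over the group. With 1 to 3 counts in the group, the ratio of the pooled levels is given with its 95% counting interval. Levels are in CPM, the deposited counts scaled to the size of each sample with TMM factors over all 20 samples, and are given as mean ± SD. Fold changes come from the fitted models. The SE beside a log2 fold change is its absolute value divided by the square root of the F statistic of its test. It was not estimated separately, and it can be too small where a group has few counts.

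Counts were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM scaling, the filterByExpr filter and Benjamini-Hochberg adjustment over all genes tested. A gene was called changed at an adjusted p under 0.05. The H2A.Z comparison used the 12 CRISPR samples with the submission set as a covariate and 10662 genes. The NICD-ER comparison (4-OHT against ethanol) and the BioNICD comparison (wild type against the DEP mutant) used 1 model of the 8 NICD samples with a coefficient per group and 12499 genes. In the same models, the difference between the NICD-ER and BioNICD effects and the difference of the H2A.Z effect between submission sets were tested. No samples were shared between the 3 main comparisons. Biological coefficients of variation were 7.95% in the CRISPR model (9 residual degrees of freedom) and 3.58% in the NICD model (4 residual degrees of freedom). Replicate samples were compared pair by pair over genes with at least 20 counts. The mean chi-square per gene was 1.80 in the closest pair and larger in the others, where sampling noise alone gives 1. No pair was therefore counted as 1 sample, although libraries made separately from 1 culture could also exceed 1. Guide replicates 1 and 2, the only guide samples of set 1, stood at 29.2, against 1.80 to 4.40 in the other pairs within a set and 33.2 to 49.1 between guide samples of different sets.

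Gene lists were fixed before the data were examined, 26 in all. They hold the targeted genes (H2afz, H2afv, Notch1), canonical Notch targets, Notch receptors with their ligands and processing enzymes, RBPJ cofactors, H2A.Z exchange and TIP60 complexes, T cell receptor and T cell identity genes, T cell effector and cytokine genes, p53 targets, interferon-stimulated genes, G1/S and G2/M cell cycle genes, replication-dependent histone genes, histone variant genes, MYC-responsive ribosome biogenesis genes, glycolysis genes, cholesterol synthesis genes, ATF4 and unfolded protein response genes, immediate early genes, apoptosis regulators, germline genes, developmental transcription factors, and markers of B cells, myeloid cells, NK and innate lymphoid cells, erythroid cells and fibroblasts or stroma. Lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01 between genes, two-sided, and adjusted by Benjamini-Hochberg over the 19 lists tested in the H2A.Z comparison or the 21 tested in each NICD comparison. Each test was repeated with an estimated correlation, and no list passed the threshold in any of the 3 comparisons that way. The smallest adjusted p by camera was then 0.20 for H2A.Z, 0.0973 for 4-OHT and 0.0694 for BioNICD. The correlation is estimated from few samples, with 9 and 4 residual degrees of freedom in the models. A miss in that version therefore does not show that a list was unchanged. Genes named below were chosen by a rule fixed before the data were examined. It takes the 3 targeted genes, the 10 largest increases and 10 largest decreases among called genes with at least 1 CPM in the higher group and no overlap between the groups' samples, and up to 4 members of each tested list with the smallest adjusted p. Genes outside the rule are marked where they appear. Some genes that the rule takes are not reported here. Overlaps between comparisons were tested with a two-sided Fisher's exact test over genes tested in both, adjusted over 12 tests.

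On simulated counts drawn from the real means and library sizes, the H2A.Z test recovered 92.9% of 56 genes changed 1.5-fold and 97.3% of 73 genes changed 2-fold, and 4.98% of its calls were false, over 10662 genes. The NICD-ER test recovered 80.3% of 66 genes changed 1.5-fold and 92.1% of 63 changed 2-fold with 9.09% false calls, above the nominal level, over 12499 genes. The BioNICD test recovered 73.5% of 68 and 82.8% of 64 with 4.02% false calls over the same number of genes. The simulation changed only a small share of the genes, in random directions, drew samples independently and held no submission set effect. Its false-call shares therefore do not carry over to the real data, where 6874 of 10662 genes passed in the H2A.Z comparison.

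The labels give both CRISPR groups the replicate numbers 1 to 6. Deviations from the group means correlated at between 0.265 and 0.451 in all 6 same-numbered pairs. After the means of the submission sets were removed as well, the correlations ran from -0.077 to 0.121, and 1 of 6 controls correlated best with the sample of its own number. The pairing therefore comes from the submission set, which the model of the H2A.Z comparison holds as a covariate.

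Alternatives fixed before the data were examined were other scalings (RLE and upper quartile), DESeq2 1.42.0 in place of edgeR, no filter or a CPM filter, a further 2-fold threshold, the replicate number as a block, other sets of samples in the model, each submission set alone, and leaving out each sample in turn. Further alternatives were chosen after seeing the data. They leave out the genes Rn45s, Lars2 and Mir6236, the 3 samples highest in Rn45s, or genes on chromosomes 5 and 8, leave out each sample in turn for both tests of a difference, or use an estimated correlation in set 2 alone and without chromosomes 5 and 8. Edits at the targeted loci, H2A.Z protein and chromatin binding were not analysed here, and no samples with BirA alone were analysed here.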

Results

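RNA was sequenced from 20 samples of the mouse T cell hybridoma E2-10HA, a line made by fusing T cells with a tumour line. They comprised 6 CRISPR controls, 6 samples with guides against both H2A.Z genes, 2 samples each with wild-type BioNICD and with its DEP mutant, and 2 samples each of NICD-ER cells with ethanol and with 4-OHT. The series asked how gene expression changed with overexpression of NICD, the signalling form of the Notch receptor, and with knockout of H2A.Z, a variant of histone H2A. Total counts ran from 10704131 to 15440584 in the CRISPR controls and from 13309111 to 18344298 with the guides. The NICD samples held 16371601 to 48238324 counts. Rn45s, the ribosomal RNA precursor, held 6.73% of the counts in control replicate 6, 7.67% in guide replicate 5 and 6.93% in guide replicate 6, against 2.46% to 3.42% in the other 9 CRISPR samples.

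Both targeted genes were lower in every sample with the guides than in any control. H2afz (mm9 chromosome 3, 137527451 to 137529886, 5 exons) stood at 5.19 ± 0.44 CPM with the guides and 28.2 ± 2.50 CPM in the control (SD, n = 6 each), with ranges of 4.55 to 5.70 and 24.7 to 31.0 CPM. Its log2 fold change was -2.44 (SE 0.084, adjusted p = 7.2e-13, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). H2afv (chromosome 11, 6327229 to 6344446, 5 exons) stood at 36.0 ± 12.0 against 127 ± 11.8 CPM, a log2 fold change of -1.87 (SE 0.098, adjusted p = 1.21e-10), with ranges of 27.3 to 56.6 and 116 to 149 CPM. The log2 fold change of H2afv was -1.46 in submission set 1 and -2.08 in set 2, and the difference passed the test (-0.63, SE 0.123, adjusted p = 0.00374), while H2afz gave -2.44 and -2.43. Notch1, at 2.68 ± 0.593 against 2.00 ± 0.697 CPM, missed the threshold (log2 fold change 0.43, SE 0.195, adjusted p = 0.0651) and passed it in some alternatives. Of these 3 genes, 0 were higher and 2 lower over all genes tested, and 1 and 2 when adjusted over the list alone. Without guides, H2afv also varied between groups, at 68.3 CPM with wild-type BioNICD, 120 CPM with the DEP mutant and 76.1 CPM in NICD-ER cells with ethanol. Counts over whole exons do not show whether the remaining transcripts were edited.

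**Figure D1:**
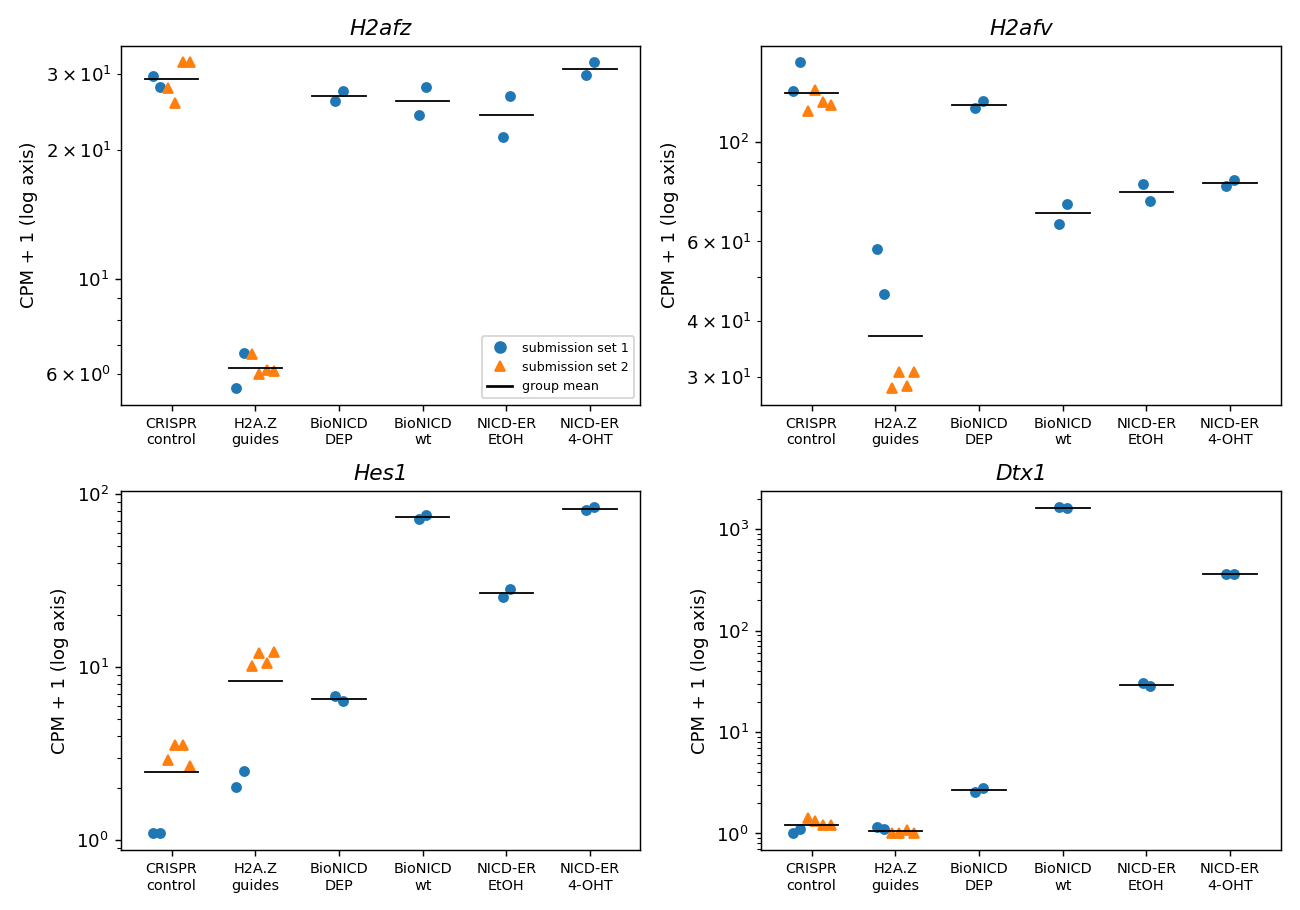
Levels of H2afz, H2afv, Hes1 and Dtx1 in each sample, as CPM + 1 on a log axis, by group; circles are submission set 1 (and all NICD samples), triangles set 2, and lines group means. H2afz averaged 5.19 CPM with the H2A.Z guides and 23.1 to 29.9 CPM in the 5 other groups. H2afv averaged 36.0 CPM with the guides and 68.3 to 127 CPM in the others. Dtx1 reached 363 CPM with 4-OHT and 1629 CPM with wild-type BioNICD against 0.0569 CPM with the guides.

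With the H2A.Z guides, the largest fitted differences were genes at or near 0 in one group and well expressed in the other. Ccdc91 reached 397 ± 65.7 CPM with the guides against 0.125 ± 0.0798 CPM in the control (log2 fold change 11.48, n = 6 each). Its control samples held 2 counts in set 1 and 8 in set 2, and the sets alone gave 12.16 and 11.25. Fcgr2b, an inhibitory Fc receptor, stood at 287 ± 22.4 against 0.101 ± 0.0918 CPM (11.33). Dpep1, a dipeptidase gene, stood at 249 ± 83.1 against 0.13 ± 0.122 CPM (10.92), and Lonrf3 and Cnn3 gave log2 fold changes of 9.93 and 8.88. The control had 1 count of E2f6 and 1 of Eno2, with pooled ratios of 1084 (95% counting interval 194 to 42840) and 1073 (192 to 42430). It had none of Lonrf1, Gm10451 and Mrvi1, which were at least 147-fold, 122-fold and 123-fold higher with the guides. In the other direction, Clec2f, a C-type lectin gene, had no counts with the guides against 34.9 ± 2.81 CPM in the control and was at least 1058-fold lower. Plekha7 and Ptpn3 were at least 322-fold and 306-fold lower. Hecw2 fell from 304 ± 9.62 to 0.731 ± 0.226 CPM (-8.69) and Klhl6 from 62.4 ± 1.91 to 0.0805 ± 0.0696 CPM (-9.50). Prelid2, Tmem205, Cd48 and Cldn12 each had 1 count with the guides, with pooled ratios of control over guides of 1420 (254 to 56120), 1032 (185 to 40820), 886 (159 to 35040) and 911 (163 to 36030). In each of these genes the 6 samples of one group lay above the 6 of the other, which the naming rule required.

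In total, 6874 of 10662 genes passed the edgeR test, 3390 higher and 3484 lower with the guides, and 538 and 449 of them changed at least 2-fold. Within submission set 1 alone (2 against 2) 2948 genes passed and within set 2 alone (4 against 4) 7756 did. Of 10523 genes tested in both sets, 2738 were called in both and 98.8% of these had the same direction. Without the 3 samples highest in Rn45s, 5869 passed. The effect differed between the sets in 1672 genes (873 with a higher and 799 with a lower log2 fold change in set 2). That count was 851 without control replicate 1, 1037 without control replicate 2, 4062 without guide replicate 2 and 447 without the 3 samples highest in Rn45s.

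Of 97 genes with a fitted difference of at least 32-fold, 35 were higher with the guides and 62 in the control. Of the 35, 23 reached 1 CPM in the DEP mutant or in NICD-ER cells with ethanol, and of the 62, 51 reached it in both of those lines. Genes on chromosome 8 had a median log2 fold change of 0.49 (95% bootstrap interval 0.48 to 0.54, 94.2% of 451 genes above 0) and those on chromosome 5 of -0.33 (-0.37 to -0.30, 552 genes). No other chromosome had a median beyond 0.1 in absolute size. Of the genes tested and named for this comparison, Dpep1, Lonrf1 and Junb are on chromosome 8 and Cldn12 and Lfng on chromosome 5.

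**Figure D2:**
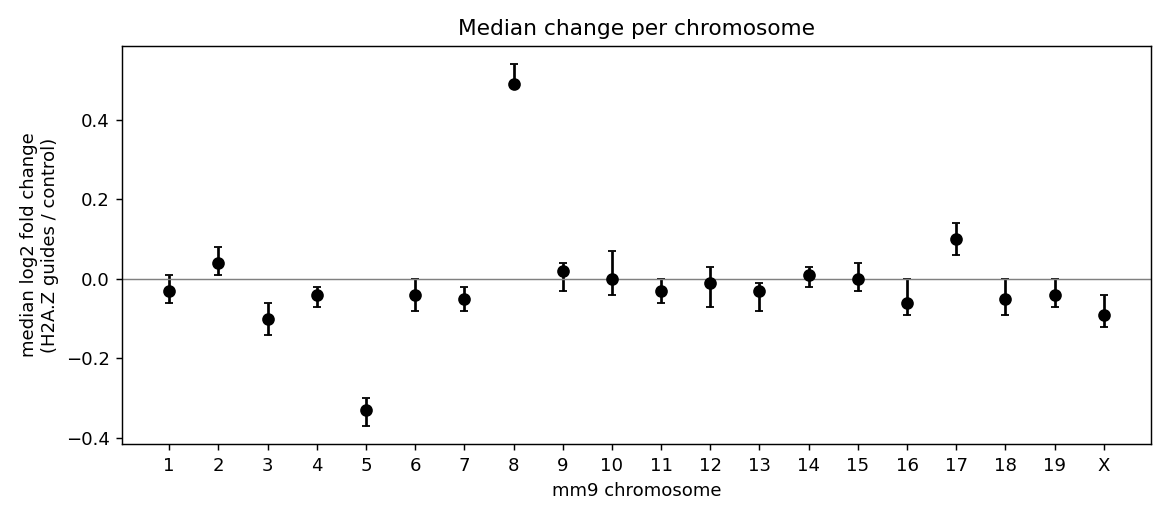
Median log2 fold change (H2A.Z guides over CRISPR control, vertical axis) of genes with a mean log2 CPM above 3, by mm9 chromosome; bars are 95% bootstrap intervals from 200 draws. Chromosome 8 lies at 0.49 and chromosome 5 at -0.33.

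Cholesterol synthesis genes were lower with the H2A.Z guides, 15 of 20 members falling and 0 rising, with the same counts when adjusted over the list alone (camera, adjusted p = 0.000112, lost with an estimated correlation at adjusted p = 0.20). Lss, the lanosterol synthase gene, fell from 723 ± 93.4 to 269 ± 47.6 CPM (log2 fold change -1.44, SE 0.039), Fdft1, squalene synthase, from 205 ± 23.8 to 94.1 ± 7.49 CPM (-1.13), Pmvk by 1.00 and Stard4 by 0.76 on the log2 scale. Of 21 glycolysis genes 17 fell and 4 rose, again the same adjusted over the list alone (camera, adjusted p = 0.011, and adjusted p = 0.20 with an estimated correlation). Aldoc, an aldolase, fell from 303 ± 37.9 to 86.3 ± 13.9 CPM (-1.82) and Slc16a3, a lactate transporter, from 251 ± 7.53 to 138 ± 4.89 CPM (-0.87). Pfkfb3, which makes an activator of glycolysis, rose from 21.7 ± 1.98 to 49.4 ± 1.08 CPM (1.19) and the enolase gene Eno2 went from 1 count to 13.6 CPM. The list's median log2 fold change was -0.48 and its mean -0.01. In 100 splits of the 12 samples, 56 gave at least as many lists past the threshold, the real split included. The number of lists therefore did not stand out. Each other split mixed guide and control samples and kept the group difference within its groups, so the splits do not test single lists.

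T cell genes changed in both directions with the guides. Cd247, the zeta chain of the T cell receptor complex, rose from 0.0846 ± 0.0788 CPM in the control by a log2 fold change of 7.55 (SE 0.23). Cd4 rose from 5.11 ± 0.912 to 108 ± 59.1 CPM (4.23, with 5.26 in set 1 and 3.74 in set 2) and Cd3g from 371 ± 93.9 to 728 ± 206 CPM (0.96), while the kinase gene Lck fell from 176 ± 11.3 to 63.1 ± 14.7 CPM (-1.51). In this list of 19, 10 rose and 6 fell, and the list missed the threshold (camera, adjusted p = 0.0965). Among effector genes, 5 rose and 4 fell of 12 (adjusted p = 0.897), with Pdcd1, the inhibitory receptor PD-1, up from 276 ± 89.0 to 1023 ± 37.2 CPM (1.95). Gzma and Tnfrsf18 had log2 fold changes of -2.39 and -3.09. Of 14 canonical Notch targets 8 rose and 2 fell, which missed the threshold (adjusted p = 0.0686). Hes1, a Notch-regulated repressor (chromosome 16, 30065443 to 30067882), rose from 1.49 ± 1.13 to 7.29 ± 4.74 CPM (2.29, SE 0.159). Its control and guide levels were 0.0944 and 1.28 CPM in set 1 and 2.18 and 10.3 CPM in set 2. Tcf7 (1.09), Bcl2 (1.32) and Lfng (0.85) rose as well, and Dtx1 was under the expression filter. Apoptosis regulators included 12 that rose and 2 that fell of 19 (adjusted p = 0.0612), among them Bmf (1.62), Cflar (0.75) and Birc3 (0.61). Leaving out chromosomes 5 and 8, an alternative chosen after seeing the data, took that list past the threshold (adjusted p = 0.0289). With an estimated correlation it did not pass (adjusted p = 0.233 without these chromosomes and adjusted p = 0.20 over all genes).

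The other lists missed the threshold in the H2A.Z comparison by camera. Members higher and lower were 12 and 4 of 22 for Notch receptors, ligands and processing (adjusted p = 0.0965; Fbxw7 0.88), 8 and 5 of 23 for RBPJ cofactors (0.586; Kdm5b -1.65, Tle3 1.03), 6 and 9 of 23 for H2A.Z exchange complexes (0.543; Anp32e, an H2A.Z chaperone, -0.63). They were 6 and 3 of 17 for p53 targets (0.193; Sesn1 0.91, Bbc3 1.15), 11 and 6 of 22 for interferon-stimulated genes (0.290; Ifi27l2a -2.53, Dhx58 1.06), 5 and 13 of 24 for G1/S genes (0.175). They were 3 and 17 of 24 for G2/M genes (0.0965; Cdc20 -0.93, Mki67 0.44), 3 and 24 of 58 for replication-dependent histones (0.0980), 2 and 4 of 9 for histone variants (0.0965) and 12 and 2 of 24 for ribosome biogenesis genes (0.411). They were 5 and 11 of 21 for ATF4 and unfolded protein response genes (0.0965; Atf4 -0.87, Trib3 -0.84), 12 and 1 of 19 for immediate early genes (0.101; Junb 1.14, Ier3 -1.67) and 2 and 1 of 6 for developmental transcription factors (0.452). Test and mean differed in sign for effector genes, and median and mean for developmental transcription factors (0.02 and -1.41). Of lists with under 5 tested members, markers of B cells had 0 tested, myeloid 1 (lower), NK 2 (both higher), erythroid 1 (lower), fibroblast 2 (1 higher and 1 lower) and germline genes 3 (2 higher and 0 lower). Adjusted over the list alone, the counts of the lists in this comparison were the same except for RBPJ cofactors (7 and 5), interferon-stimulated genes (12 and 6) and G1/S genes (5 and 14), besides the targeted genes.

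In NICD-ER cells, 24 hours of 4-OHT raised known Notch targets. Hey1 (chromosome 3, 8663359 to 8667038), a repressor downstream of Notch, rose from 0.505 ± 0.164 CPM with ethanol to 45.4 ± 4.08 CPM with 4-OHT (SD, n = 2 each), a log2 fold change of 6.48 (SE 0.129, edgeR adjusted p = 2.75e-21). Dtx1 (chromosome 5, 121130273 to 121161678), an E3 ligase of the Notch pathway, rose from 28.4 ± 1.43 to 363 ± 3.18 CPM (3.68, SE 0.045). Il2ra, the alpha chain of the IL-2 receptor, rose from 86.2 ± 2.95 to 357 ± 2.85 CPM (2.05), Hes1 from 25.9 ± 2.00 to 81.6 ± 2.04 CPM (1.66), and Nrarp, a Notch feedback inhibitor, from 0.0951 ± 0.00284 to 3.80 ± 0.681 CPM (5.27). Of 19 canonical targets 10 rose and 5 fell (10 and 7 adjusted over the list alone; camera, adjusted p = 4.07e-05, and adjusted p = 0.0973 with an estimated correlation). Myc, outside the rule and chosen after its values were seen, was among those that fell (230 ± 1.77 to 109 ± 0.805 CPM, -1.08).

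Other large increases with 4-OHT were Rhov (7.57), Slc45a4 (6.04), Gcnt2 (5.86), Aldh3b1 (5.77), Tgm2 (5.73) and Mgst1 (5.34 on the log2 scale). Il10 had no counts with ethanol and was at least 33.5-fold higher with 4-OHT, and Ret had 3, with a pooled ratio of 45.1 (95% counting interval 15.2 to 221). The largest decreases were smaller. Papln fell from 21.9 ± 2.13 to 4.25 ± 0.0664 CPM (-2.36). The chemokine receptors fell as well, Cxcr6 from 24.8 ± 0.540 to 5.71 ± 0.117 CPM (-2.12) and Ccr6 from 10.4 ± 0.384 to 2.66 ± 0.372 CPM (-1.97). Zdhhc23 fell by 1.98 on the log2 scale, and Epb4.1l1 (-1.78), Trat1 (-1.71), Neurl3 (-1.58), Pipox (-1.57) and Agpat9 (-1.55) were lower too. Cxcr3 gave -1.76 (adjusted p = 0.00113), a call lost in DESeq2 (adjusted p = 0.0583) and without 4-OHT replicate 2 (adjusted p = 0.0565). In all, 4521 of 12499 genes passed the edgeR test, 2376 higher and 2145 lower, with 332 and 107 at least 2-fold. Upper quartile scaling gave 1970 higher and 2586 lower, so which direction held more genes depended on the scaling. A model over all 20 samples called 2218. Of the 4 samples, ethanol replicate 1 stood apart with 91.0 CPM of Lars2 against 2184 to 2968 CPM in the other 3, and 3580 genes passed without it.

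Cell cycle genes rose with 4-OHT by small amounts. Of 24 G1/S genes 20 rose and 1 fell, unchanged when adjusted over the list alone (camera, adjusted p = 4.45e-05; adjusted p = 0.234 with an estimated correlation). Of 24 G2/M genes 21 rose and 0 fell, 22 adjusted over the list alone (adjusted p = 1.82e-06; adjusted p = 0.244 with an estimated correlation). Tyms, thymidylate synthase, rose from 44.3 ± 1.25 to 60.6 ± 2.18 CPM (0.46), Fen1 by a log2 fold change of 0.36, the replication helicase gene Mcm4 by 0.29, and the mitotic genes Nusap1, Ccna2 and Ccnb2 by 0.33, 0.32 and 0.31. Ribosome biogenesis genes fell, 19 of 24 and 0 rising, the same adjusted over the list alone (adjusted p = 8.71e-07; adjusted p = 0.0973 with an estimated correlation), with Srm (-0.44), Polr1b (-0.46), Gnl3 (-0.35) and Mybbp1a (-0.30). Of 21 glycolysis genes 18 fell and 1, Hk1, rose (19 and 1 adjusted over the list alone; adjusted p = 1.01e-06; adjusted p = 0.0973 with an estimated correlation). Slc16a3 fell by 0.61, Aldoa by 0.44 and Gpi1 by 0.42 on the log2 scale, and Hk1, a hexokinase gene, rose from 291 ± 3.95 to 492 ± 11.1 CPM (0.76). Of 20 cholesterol synthesis genes 10 fell and 0 rose (11 adjusted over the list alone; adjusted p = 0.00207; adjusted p = 0.0973 with an estimated correlation), among them Insig1 (-0.57).

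Interferon-stimulated genes rose in 15 and fell in 3 of 30 cases with 4-OHT (17 and 3 adjusted over the list alone; camera, adjusted p = 0.00221; adjusted p = 0.234 with an estimated correlation). Isg15 rose from 5.55 ± 0.300 to 25.8 ± 0.891 CPM (2.22), and Usp18, which damps interferon signalling, fell from 61.6 ± 1.59 to 29.1 ± 1.56 CPM (-1.08). Of 5 NK and innate lymphoid markers 3 rose and 0 fell, as when adjusted over the list alone (adjusted p = 4.45e-05; adjusted p = 0.0973 with an estimated correlation). These were Il2rb (6.73 ± 0.135 to 26.5 ± 0.0160 CPM, 1.98), Id2 (0.99) and Nkg7 (1.85). Effector genes split, 6 up and 6 down of 21 (adjusted p = 0.683), with Il22 up from 0.503 ± 0.299 to 11.5 ± 0.392 CPM (4.50), the granzyme gene Gzmb up by 1.06 and Pdcd1 down by a log2 fold change of -0.91. T cell identity genes rose in 5 and fell in 10 of 24 cases (adjusted p = 0.0975), with Lck up from 154 ± 0.304 to 407 ± 6.30 CPM (1.41) and Lef1 (-1.42) down.

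Further lists missed the threshold with 4-OHT. Members higher and lower were 7 and 6 of 22 for Notch receptors, ligands and processing (adjusted p = 0.751; Furin 1.57, Jag1 1.05), 5 and 5 of 25 for RBPJ cofactors (0.883). They were 3 and 1 of 23 for H2A.Z exchange complexes (0.903), 4 and 4 of 17 for p53 targets (0.594), 9 and 11 of 58 for replication-dependent histones (0.757), 5 and 1 of 9 for histone variants (0.460) and 3 and 12 of 22 for ATF4 and unfolded protein response genes (0.112). They were 6 and 8 of 21 for immediate early genes (0.683), 7 and 5 of 19 for apoptosis regulators (0.683), 0 and 2 of 7 for germline genes (0.751) and 2 and 1 of 9 for developmental transcription factors (0.751). Median, mean and test differed in sign for Notch receptors, RBPJ cofactors, H2A.Z exchange, p53 targets, histones, germline genes and developmental transcription factors. Markers of B cells had 1 higher and 0 lower of 2 tested, myeloid 1 and 1 of 4, erythroid 1 and 0 of 4 and fibroblast 1 and 2 of 4. Of the targeted genes, H2afz was higher with 4-OHT (29.9 against 23.1 CPM, log2 fold change 0.38, SE 0.086, adjusted p = 0.00131), and H2afv (0.07, adjusted p = 0.272) and Notch1 (-0.09, adjusted p = 0.0807) missed the threshold. Adjusted over the list alone, counts of these lists were the same except 4 and 7 for p53 targets, 3 and 13 for ATF4 and unfolded protein response genes, 1 and 1 for developmental transcription factors and 1 and 1 for the targeted genes. Notch1 stood at 98.4 CPM with ethanol and 92.0 CPM with 4-OHT, against 2.00 CPM in the CRISPR control, so its counts may come largely from NICD-ER. Cells treated with 4-OHT in the absence of NICD-ER were not analysed here.

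**Figure D3:**
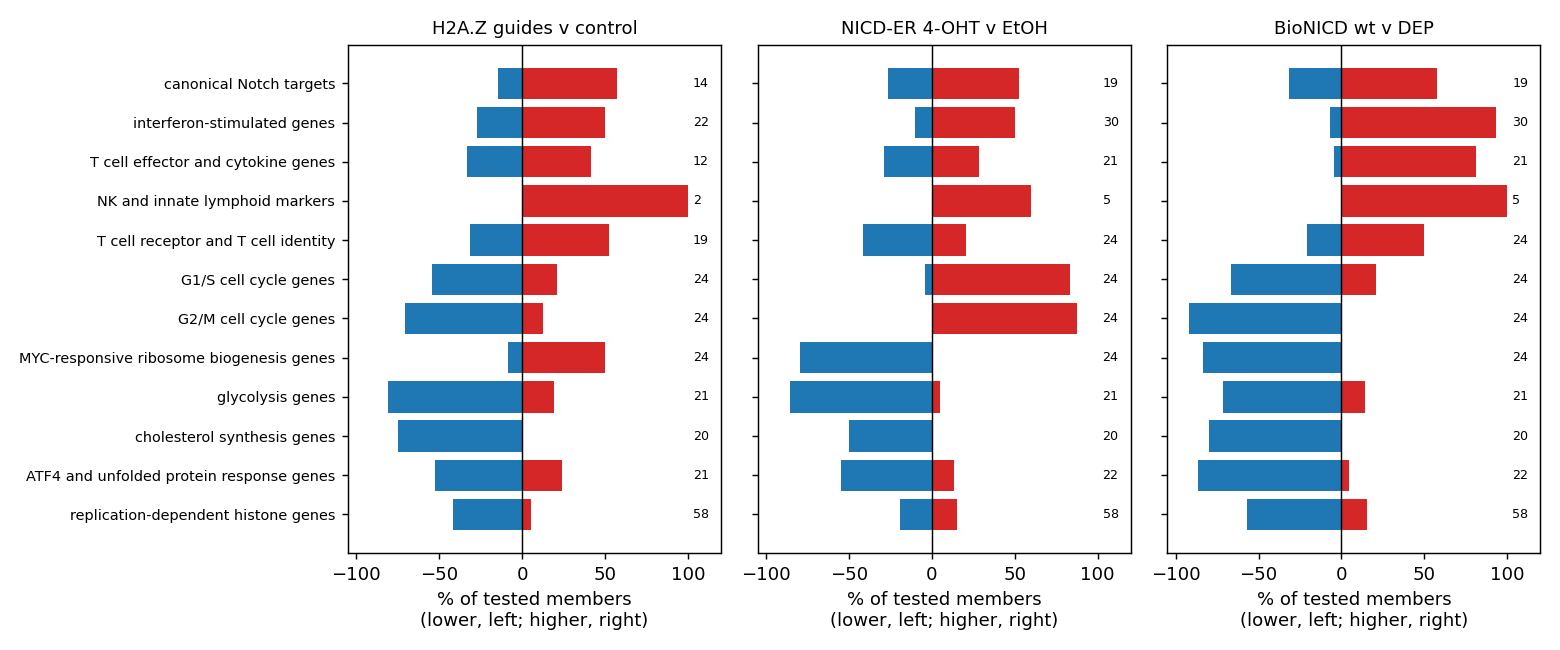
Share of tested members (horizontal axis, %) that were lower (left, blue) or higher (right, red) at an adjusted p under 0.05, for 12 lists in the 3 comparisons; the number beside each bar is the members tested. Among G2/M genes 21 of 24 rose with 4-OHT, and 22 of 24 were lower in wild-type BioNICD than in the DEP mutant.

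Wild-type BioNICD and the DEP mutant differed more widely. Dtx1 stood at 1629 ± 19.6 CPM with the wild type and 1.71 ± 0.170 CPM with the mutant (SD, n = 2 each; log2 fold change 9.86, SE 0.069, edgeR adjusted p = 1.82e-30), Il2ra at 542 ± 11.2 against 0.377 ± 0.134 CPM (10.50) and Hey1 at 434 ± 1.73 against 0.470 ± 0.331 CPM (9.74). Cd44, an adhesion receptor, was lower with the wild type (28.8 ± 0.0604 against 189 ± 5.51 CPM, -2.73). Of 19 canonical Notch targets 11 were higher and 6 lower, the same adjusted over the list alone (camera, adjusted p = 0.00334; adjusted p = 0.237 with an estimated correlation). Notch1 (chromosome 2, 26313422 to 26359342) had 643 ± 20.9 CPM in the mutant and 282 ± 11.3 CPM in the wild type (-1.20, SE 0.038). The CRISPR control, which carried no NICD, had 2.00 ± 0.697 CPM, which argues against the endogenous gene as the source of most of these reads. The counts themselves do not separate the transgene from the endogenous gene. Notch1 also counts as lower among the targeted genes, the canonical Notch targets and the Notch receptors. H2afv was lower with the wild type (-0.84) and H2afz gave -0.08 (adjusted p = 0.487), so 0 of the targeted genes were higher and 2 lower, also when adjusted over the list alone.

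By fitted fold, which depends on the prior count where a group has no counts, most of the largest increases were genes without counts in the mutant. Crxos had 142 ± 4.78 CPM with the wild type and was at least 1798-fold higher than with the mutant, Adam19 at least 560-fold, Slit3 418-fold, Cd244 370-fold, Dcdc2c 337-fold, Csn1s1 316-fold, Iqsec3 281-fold, Vwa5b1 258-fold and Serpina3g 232-fold. Blk, a kinase of the Src family best known from B cells, had 241 ± 1.79 CPM against 1 count in the mutant, a pooled ratio of 9221 (95% counting interval 1655 to 364200). In the other direction Col11a1 and Tex26 had 2 counts each with the wild type (pooled ratios 123, 33.4 to 1029, and 39.5, 10.3 to 337), and Cfap221 (-4.25), Arhgap36 (-3.96), 1500009L16Rik (-3.91), Fat1 (-3.86), Trat1 (-3.68), the chemokine receptor gene Ccr2 (-3.61), 5830411N06Rik (-3.50) and Galnt3 (-3.38) were lower. In all, 8194 of 12499 genes passed, 3999 higher and 4195 lower with the wild type, with 1390 and 432 at least 2-fold. The labels name no independent lines of either protein.

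Cytotoxic and cytokine genes were higher with wild-type BioNICD, 17 of 21 effector genes rising and 1 falling, as when adjusted over the list alone (camera, adjusted p = 9.54e-17; adjusted p = 0.0694 with an estimated correlation). Gzmb stood at 5009 ± 71.2 against 18.7 ± 0.557 CPM (8.05, SE 0.051), Gzma at 1027 ± 51.3 against 7.52 ± 0.792 CPM (7.06) and the cytokine gene Il10 at 200 ± 7.70 against 0.212 ± 0.0339 CPM (9.85). Prf1, perforin, had 340 ± 8.48 CPM against 3 counts in the mutant, a pooled ratio of 4362 (1492 to 21150). All 5 tested NK and innate lymphoid markers were higher, also adjusted over the list alone (adjusted p = 8.03e-16; adjusted p = 0.0694 with an estimated correlation), among them Il2rb (5.58), Id2 (2.65), Nkg7 (9.76) and Gzmc (pooled ratio 146, 49.6 to 707). Interferon-stimulated genes were higher in 28 and lower in 2 of 30 cases, the same adjusted over the list alone (adjusted p = 6.22e-28; adjusted p = 0.0787 with an estimated correlation), with Isg15 4.67, Zbp1 4.57 and Oas3 2.48. T cell identity genes were higher in 12 and lower in 5 of 24 cases, the same adjusted over the list alone (adjusted p = 0.00694; adjusted p = 0.190 with an estimated correlation), with Ets1 at 69.8 ± 2.42 against 0.235 ± 0.000723 CPM (8.17), Cd6 5.02, Lck 1.44 and Cd28 1.44.

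With wild-type BioNICD, G2/M genes fell in 22 and rose in 0 of 24 cases (camera, adjusted p = 8.98e-06; adjusted p = 0.237 with an estimated correlation), with Hmmr -0.68, Cdc20 -0.67 and Cdk1 -0.61. Ribosome biogenesis genes fell in 20 of 24 cases and rose in 0 (adjusted p = 0.000163; adjusted p = 0.175 with an estimated correlation), with Gnl3 -0.90 and Nop58 -0.58. Cholesterol synthesis genes fell in 16 of 20 and rose in 0 (adjusted p = 8.51e-08; adjusted p = 0.0694 with an estimated correlation), with Msmo1 -1.26 and Insig1 -1.25. ATF4 and unfolded protein response genes fell in 19 and rose in 1 of 22 cases (adjusted p = 1.76e-06; adjusted p = 0.159 with an estimated correlation), with the endoplasmic reticulum chaperone gene Hsp90b1 -0.97, Herpud1 -0.89 and Atf4 -0.75. H2A.Z exchange and TIP60 genes fell in 14 and rose in 3 of 23 cases (adjusted p = 0.0269; adjusted p = 0.175 with an estimated correlation), with Anp32e -0.96, Brd8 -0.60 and Ruvbl2 -0.56. Replication-dependent histone genes fell in 33 and rose in 9 of 58 cases (adjusted p = 0.0146; adjusted p = 0.658 with an estimated correlation), with Hist2h2be -1.96 and Hist1h2af -0.80. Adjusted over the list alone these counts were the same, with 34 in place of 33 histone genes lower.

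The remaining lists missed the threshold between wild-type BioNICD and the mutant. Members higher and lower were 9 and 4 of 22 for Notch receptors, ligands and processing (adjusted p = 0.401), 10 and 11 of 25 for RBPJ cofactors (0.852), 8 and 5 of 17 for p53 targets (0.852). They were 5 and 16 of 24 for G1/S genes (0.0663), 2 and 6 of 9 for histone variants (0.0511), 3 and 15 of 21 for glycolysis genes (0.107), 11 and 7 of 21 for immediate early genes (0.135). They were 11 and 5 of 19 for apoptosis regulators (0.219), 2 and 2 of 7 for germline genes (0.607) and 4 and 0 of 9 for developmental transcription factors (0.699), all the same adjusted over the list alone. The mean of RBPJ cofactors (0.09) and the median of germline genes (-0.31) had the opposite sign to the test. B cell markers were higher in 2 of 2 cases, Blk and Cd22, the latter chosen after its values were seen (1396 ± 34.9 against 0.618 ± 0.123 CPM), myeloid markers in 3 of 4, erythroid in 1 of 4 and fibroblast in 2 of 4, with 0 lower.

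The 2 NICD effects differed in 6438 of 12499 genes by the edgeR test of the difference. The log2 fold change for 4-OHT against ethanol was higher than that for wild type against the mutant in 3304 and lower in 3134 (3025 and 3307 with RLE scaling). All 24 G2/M genes passed this test, each higher in the NICD-ER effect (Ccna2 0.73, Cdc20 0.70, Cdk1 0.69), as did 28 of 30 interferon-stimulated genes, each lower (Isg15 -2.45). Effector genes differed in 14 lower and 1 higher of 21 cases (Gzmb -6.99, SE 0.0599, and Gzma -7.42), and canonical Notch targets in 10 lower and 5 higher of 19 (Dtx1 -6.18, Hey1 -3.26 and Hes1 -2.04). Lck, with -0.03 (SE 0.0495), did not pass. These members were counted after both effects had been seen. The NICD-ER effect compares 24 hours of ligand with ethanol, and the BioNICD effect compares samples that express different proteins. Il2ra stood at 86.2 CPM with ethanol and 0.377 CPM in the mutant, and Notch1 at 92.0 CPM with 4-OHT and 282 CPM with wild-type BioNICD. Time, NICD level, baseline and line therefore cannot be told apart as sources of the difference.

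Genes changed by NICD in one system tended to change in the same direction in the other. Of 2376 genes higher with 4-OHT, 1338 were also higher with wild-type BioNICD where independent lists would share 760.2 (odds ratio 3.61, Fisher's exact test, adjusted p = 2.29e-164), and 1294 were lower in both where 719.9 were to be shared (3.91, adjusted p = 4.83e-172). Opposite directions were under-represented (549 up then down, odds ratio 0.534, adjusted p = 2.56e-34; 380 down then up, 0.401, adjusted p = 1.06e-58), except that with a 2-fold threshold the odds ratio of down then up was 1.97. Across 12499 genes the log2 fold changes correlated at r = 0.496 (Spearman's rho 0.333), and 73.9% of 3561 genes called in both had the same direction. Genes are not independent replicates, so these tests describe the gene sets of these samples.

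The H2A.Z comparison overlapped the NICD comparisons less. Of 2173 genes higher with 4-OHT and tested in both, 698 were higher with the guides (690.4 if independent, odds ratio 1.02, adjusted p = 0.699) and 768 lower (710.2, odds ratio 1.16, adjusted p = 0.00384). Of 2095 genes lower with 4-OHT, 660 were lower with the guides (684.7, odds ratio 0.935, adjusted p = 0.222) and 851 higher (665.6, odds ratio 1.63, adjusted p = 1.87e-21). Of genes higher with wild-type BioNICD, 1363 were higher with the guides (1036.7, odds ratio 1.90, adjusted p = 1.82e-47) and 891 lower (1066.4, odds ratio 0.696, adjusted p = 3.25e-15), and of those lower with it, 1556 were lower (1322.3, odds ratio 1.52, adjusted p = 8.2e-23) and 1045 higher (1285.5, odds ratio 0.635, adjusted p = 5.54e-25). With a 2-fold threshold in both comparisons every pair of directions of both NICD comparisons with the guides was over-represented, with odds ratios of 3.13 to 8.47, so the direction of these overlaps depended on the threshold. Log2 fold changes of the H2A.Z comparison correlated across genes at r = -0.008 (rho -0.044) with the 4-OHT effect and at 0.07 (rho 0.14) with the BioNICD effect, with the same direction in 45.6% of 2977 and 60.1% of 4855 genes called in both.

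Taken as sets, genes that responded to NICD did not pass in the H2A.Z comparison by camera. Genes higher with 4-OHT had a median log2 fold change of -0.02 with the guides, opposite in sign to their mean and test (adjusted p = 0.845), genes lower with 4-OHT 0.04 (adjusted p = 0.224), genes higher with wild-type BioNICD 0.08 (adjusted p = 0.195) and genes lower with it -0.07 (adjusted p = 0.195). In submission set 2 alone the BioNICD sets passed (adjusted p = 0.0217 for the genes higher with the wild type and 0.0234 for those lower), and in set 1 alone they did not (adjusted p = 0.991 for both). With an estimated correlation these BioNICD sets had adjusted p = 0.00203 and 0.00507 in set 2 alone, a setting chosen after seeing the data, and adjusted p = 0.554 for both over all 12 samples. The difference between the submission sets was not tested for these gene sets.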

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

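The test of the difference between submission sets and the tests of ribosomal RNA and of H2afv were set before their results were seen, and the matched left-out samples used as a control for ribosomal RNA were chosen only after 447 had been seen. The share among genes with the same sign in both sets was also chosen after the share over all genes had been seen. Alternatives of the set difference were also chosen after seeing the data.

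Some named genes responded to the H2A.Z guides by different amounts in the submission sets, by a test of the difference itself. The effect of set 2 minus that of set 1, on the log2 scale, was -1.53 for Cd4, -0.97 for Pdcd1, -0.85 for Bcl2, -0.53 for Tcf7, -0.40 for Kdm5b and -0.42 for Cdc20. It was 1.58 for Gzma, 0.85 for Tnfrsf18, 0.54 for Lck and 0.50 for Fdft1, all of which kept the sign of their effect within each set. Over all genes that passed and had a value in both sets, 1000 of 1666 had the same sign in both. H2afv gave -0.63, while H2afz gave -0.01. The test uses 1 estimate of the spread per gene for all 12 samples, while guide replicates 1 and 2, the only guide samples of set 1, stood further apart (mean chi-square 29.2) than other pairs within a set (1.80 to 4.40). Cnn3 gave 5.26 at an edgeR adjusted p of 0.0499 on a control level of 5 counts in all.

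Over all genes the difference passed in 1672 of 10662, with 851 without control replicate 1, 1037 without control replicate 2 and 4062 without guide replicate 2. A deeper loss of H2afv in set 2 was predicted to give most of these genes the larger effect there. Of the 1666, 45.7% had it, or 44.2% of the 1000 with the same sign. Set 1 had fewer samples and guide samples that stood far apart, so its noisier estimates can be the larger among genes selected for a difference. The share therefore cannot decide on that explanation. Ribosomal RNA may contribute, since 447 genes passed without the 3 samples highest in Rn45s, all of set 2. Leaving out 3 other samples of set 2, matched by group, gave 578, 575 and 505, so a contribution of ribosomal RNA and the loss of samples cannot be told apart. A biological difference between the sets was not tested, because the labels name none.

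Within groups of 6 samples, 13 of 109 groups of values had a sample whose gap to the nearest other, over the range of the group, exceeded Dixon's 95% critical value. For normal values of 1 population chance gives about 1 in 20, and these groups span both submission sets. Most were genes near 0 in that group, where a few counts set the value: Fcgr2b at 0.275 CPM in control replicate 3, E2f6 at 0.0940 CPM and Cnn3 at 0.470 CPM in control replicate 1, and Eno2 at 0.0657 CPM in control replicate 4. With the guides these were Prelid2 at 0.0559 CPM in replicate 2, Tmem205 at 0.0648 CPM in replicate 4, Cd48 at 0.0653 CPM in replicate 6 and Cldn12 at 0.0746 CPM in replicate 1. Among expressed genes, control replicate 1 stood apart for Clec2f (29.3 CPM) and Kdm5b (203 CPM), control replicate 3 for Cd48 (7.49 CPM), and guide replicate 2 for Pdcd1 (952 CPM) and Tle3 (157 CPM).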

How the results depend on the processing

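Alternatives that leave out Rn45s, Lars2 and Mir6236, the 3 samples highest in Rn45s, or chromosomes 5 and 8, an estimated correlation in set 2 alone, and all alternatives of the set difference, were chosen after seeing the data. A 2-fold threshold left 987 genes in the H2A.Z comparison, 439 with 4-OHT and 1822 between wild-type BioNICD and the mutant. Set 1 alone gave 2948 genes for H2A.Z, with fewer samples, and a model of all 20 samples gave 2218 for 4-OHT; the cause was not tested. Other counts stayed within 1.5 times, from 5644 (no set term) to 7756 (set 2 alone) for H2A.Z, from 3334 (DESeq2) to 4991 for 4-OHT and from 6491 (all 20 samples) to 8371 for BioNICD. Leaving out 1 sample gave 6582 to 7397, 3107 to 4251, 7236 to 7807, and 5599 to 6258 for the difference between the NICD effects. In both NICD comparisons that leaves a lone sample, which is assumed to vary like the other groups. The set difference ranged from 851 to 4062, and was 447 without the 3 samples highest in Rn45s. Which direction held more genes turned under RLE scaling for H2A.Z (3469 higher, 3410 lower), BioNICD (4131 and 4002) and the difference between the NICD effects. For 4-OHT it turned under upper quartile scaling. Settings other than scaling turned it too. These included no filter (3764 and 3521) and set 1 alone (1563 and 1385) for H2A.Z. For BioNICD they included DESeq2 (3678 and 3353) and a model of all 20 samples (3345 and 3146).

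With a 2-fold threshold the odds ratio of the overlap became 4.45 (4-OHT and guides, both up), 7.73 (both down), 4.63 (BioNICD up, guides down), 6.48 (BioNICD down, guides up) and 1.97 (4-OHT down, BioNICD up). The last 4 reversed; the cause was not tested. With DESeq2, over genes with an adjusted p in both, 4-OHT and guides both up gave 1.24, past the threshold, and BioNICD down with guides up gave 0.975, no longer past it. In set 2 alone the BioNICD gene sets passed in the H2A.Z comparison (camera, adjusted p = 0.0217 and 0.0234; adjusted p = 0.00203 and 0.00507 with an estimated correlation, against 0.554 for both over all 12 samples). With an estimated correlation 0 lists passed in each comparison, also for H2A.Z without chromosomes 5 and 8. None of 58, 56 and 59 named genes reversed. Notch1 passed in 5 alternatives for H2A.Z and 3 for 4-OHT, and Cxcr3 was lost in 2.

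With the replicate number as a block, 6412, 4991, 8371 and 6717 genes passed for H2A.Z, 4-OHT, BioNICD and the difference between the NICD effects. The adjusted p of the 4 NICD gene sets in the H2A.Z comparison was 0.857, 0.201, 0.175 and 0.175, and 2, 8 and 13 lists passed. Same-numbered NICD samples share only a number, with deviations that correlated at 0.035 (NICD-ER) and -0.005 (BioNICD). The block took canonical Notch targets from past the threshold to camera adjusted p values of 0.0797 (4-OHT) and 0.104 (BioNICD), and took past it unfolded protein response genes with 4-OHT (0.0303) and G1/S, histone variant and glycolysis genes with BioNICD (0.0348, 0.0441 and 0.0397). In the H2A.Z comparison it took Notch1 past the threshold (0.0481) and changed no other call on a list or named gene.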

Other observations

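Tests of scaling and of H2A.Z acting on chromosomes 5 and 8, all 4 tests of genes with large differences between the CRISPR lines, and the DEP mutant as a control for NICD-ER activity were chosen only after the result was seen.

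Some genes known from other blood and stromal lineages were higher with wild-type BioNICD than with the mutant, and Cd22 and Spi1 rose with 4-OHT. The genes named here were chosen after their values were seen, and lists of B cell, myeloid, erythroid and fibroblast markers had at most 4 members tested. The list of germline genes had 2 higher and 2 lower of 7 with wild-type BioNICD (camera, adjusted p = 0.607). Cd22, a B cell lectin, rose from 9.68 ± 2.15 to 162 ± 1.02 CPM with 4-OHT (log2 fold change 4.07, n = 2 each), and Spi1, a myeloid and B cell transcription factor, from 0.0944 ± 0.0420 to 1.01 ± 0.118 CPM (3.36). Itgam, an integrin of myeloid and NK cells, stood at 62.2 ± 1.15 CPM with wild-type BioNICD and 0.135 ± 0.0587 CPM with the mutant (8.83), and Spi1 at 7.73 ± 0.0141 against 0.135 ± 0.0587 CPM (5.82). Pdgfrb, a stromal growth factor receptor, stood at 115.0 ± 2.16 against 0.0705 ± 0.0996 CPM (10.43), and the germline gene Tdrd9 at 43.6 ± 0.557 against 0.241 ± 0.0756 CPM (7.49). Lyz2, abundant in myeloid cells, was at 0.164 ± 0.00461 CPM with wild-type BioNICD. With the H2A.Z guides, Il2rb rose from 6.04 ± 1.57 to 50.7 ± 14.9 CPM (3.06) and Id2 from 35.6 ± 13.2 to 105.5 ± 5.00 CPM (1.62), while Cd68 (-1.65) and Acta2 (-1.73) fell and Vim (0.68), the other fibroblast marker tested, rose.

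Genes of chromosome 8 were higher with the H2A.Z guides (median log2 fold change 0.49, 388 higher and 15 lower) and those of chromosome 5 lower (-0.33, 101 higher and 359 lower). Scaling would move all chromosomes, and the other 18 had medians of at most 0.1 in absolute size, while medians after a fit on GC content, exon length and expression were 0.49 and -0.32. A candidate explanation is a different copy number of these chromosomes in the lines, since 13 of 13 windows of 10 Mb on chromosome 8 and 13 of 15 on chromosome 5 lay on the side of the whole chromosome, with similar medians in both sets (0.53 and 0.50, and -0.31 and -0.32). H2A.Z loss acting on these chromosomes cannot be told apart from it, because the titles number 1 line with the guides.

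Between the CRISPR lines, 111 genes differed at least 32-fold in a model of all 20 samples. Pairs of lines without guides gave 7, 18 and 42, all fewer. These pairs share lines, rest on fewer samples and vary widely, so they set no limit on how far lines can differ. Reads carried over from NICD samples are argued against for 35 genes higher with the guides and 62 higher in the control (32-fold in the H2A.Z model), whose median levels there were 2.22 and 0.799 times the highest NICD level, while Dtx1 was at 3.49e-05 and 0.000129 of its own. Of the 35 genes, 23 reached 1 CPM in the DEP mutant or in NICD-ER cells with ethanol, which carried no guides. In the model of 20 samples the control was the lower line in all 18 and 42 genes of its pairs with these lines. That count was not taken over the 23, so it does not bear on them. Their levels argue only against loss of H2A.Z as needed to reach 1 CPM, in lines that carry NICD constructs. In the DEP mutant and with ethanol, E2f6 stood at 12.3 and 15.5 CPM, against 13.7 CPM with the guides. Fcgr2b stood at 1.05 and 8.62 CPM there, against 287 CPM with the guides, so a need for the guide level stays open. A change in the control line itself was not tested. Beyond that, loss of H2A.Z and cloning of either line cannot be told apart, because the titles number 1 line with the guides.

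Of 100 splits of the CRISPR samples, only the real one gave 6874 genes in the H2A.Z comparison, and the highest other gave 1433. Every other split mixed guide and control samples, so the group difference widened its spread. With 1 line of guide samples, the splits cannot exclude a chance difference between the lines. For the lists, 56 of 100 splits gave at least the real 2 and the highest other gave 8. Chance was therefore not excluded for the lists either.

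A hypothesis that NICD-ER was active without 4-OHT was tested on genes at least 2-fold higher in both NICD comparisons. Of 250 such genes 77.2% were higher with ethanol than in the CRISPR control, against 52.0% of all genes, with 123 called higher and 8 lower by edgeR. In the DEP mutant 62.8% were higher than in the control, against 51.7% of all genes. These genes were selected for being lower with ethanol and in the mutant than in the partner samples. Activity without 4-OHT may contribute but cannot be told apart from a difference between the lines, since NICD-ER cells and the control are 1 line each.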
